A study of Mus musculus with 12 samples.

How the data were processed

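Gene expression was measured by RNA sequencing of whole mouse lung in 12 libraries. Per the labels' protocols, RNA was isolated with TRIzol 14 to 16 h after treatment, libraries were made with an Illumina TruSeq total RNA kit, and 100-base single-end reads were sequenced on an Illumina HiSeq instrument. Per the series' design text, reads were trimmed of adaptors, masked for low quality and mapped to mouse genome mm9 with TopHat, version 2.0.8b in the submitters' processing notes, and genes were quantified with HTSeq and DESeq. The processing notes also name bcl2fastq. The version, annotation and strand setting of HTSeq are not given in the sources used here. Reads of a gene and of an antisense or overlapping gene can therefore not be told apart, and genes with near-identical copies (Ly6, Gbp, Slfn, Oas1, Ifi200 and H2 families, Saa1 and Saa2, Rprl genes) are uncertain, since reads with several alignments were set aside in the deposited tables.

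The deposited values are raw counts per gene, 1 table per library, as whole numbers with no normalization by the authors. The tables of the RNase III set list 33924 genes and those of the knockout set 22609. All of the first and 95.7% of the second are in GENCODE mouse release 1 (NCBIM37), which gave the coordinates printed, and 21627 gene symbols are shared. The last lines of each table hold HTSeq's totals of reads not assigned to a gene. They were kept out of library sizes and tests. Of the reads in each table, 23.1% to 28.2% were assigned to genes, 27.0% to 40.0% had no feature, 36.8% to 44.6% were not uniquely aligned and 0.0552% to 0.172% were ambiguous. Assigned reads numbered 17754518 to 25714074 per library in the RNase III set and 15687699 to 20945618 in the knockout set. A count of 0 allows up to 3 counts, or 0.117 to 0.191 CPM depending on the library. The 10 most abundant genes took 11.3% to 14.3% of assigned reads in the RNase III set and 7.54% to 9.00% in the knockout set.

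Groups and replicate numbers were taken from the sample titles. The groups, the comparisons, the tests, the alternatives, 49 gene lists and the rule for naming genes were fixed before the data were examined. Counts were analysed in R 4.3.3 with edgeR 4.0.16, using TMM normalization, filterByExpr by group, glmQLFit and glmQLFTest, and Benjamini-Hochberg adjusted p below 0.05 as the threshold. Each set was fitted on its 6 libraries with a mean per group, which left 3 residual degrees of freedom in the RNase III set and 2 in the knockout set. In the knockout set each genotype has 1 PBS library, and that library is assumed to vary like the replicated groups. The response of wild-type lung was also fitted over the 7 wild-type libraries with PBS or untreated D.f. extract in both sets, with the set as a term. Levels are CPM with TMM-scaled library sizes, as mean ± SD, and log2 fold changes are given ± SE. The difference between the PBS libraries of the knockout set has no replicate check and no p-value.

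Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and the rotation test fry were run beside it, and members were counted by adjusted p over all genes and over the list alone. Lists called in one set were tested in the other set, which shares no library with it. Overlaps of calls used Fisher's exact test over the genes tested in both. For comparisons that share PBS libraries, 50 simulations of unchanged groups gave the values set beside the observed ones. Replicates were compared by a chi-square over genes.

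Named genes followed a fixed rule. Per comparison these were up to 10 genes with the largest rise and 10 with the largest fall among called genes with a mean log2 CPM of at least 1 whose libraries did not overlap between groups, passing over unnamed gene models. To these were added the 4 members with the smallest p of each list called by camera, or up to 4 of a list described, and Tlr3, Mavs, Ifnb1, Ifng, Isg15, Cxcl10, Il33, Il13, Ccl11, Muc5ac, Cxcl1 and Il6 in each comparison. Up to 20 genes called in the same direction for RNase III and for the knockout completed the rule. For the interaction the condition on overlap was dropped. Outside the rule, Saa3 in the knockout libraries, Myh6, Ifna2, and Psca and other genes that separated the genotypes were chosen after their values were seen.

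The analysis was tested on simulated data with 200 changed genes in each of 5 draws from the real means and library sizes. For D.f. against PBS in the RNase III set (17165 genes), 43.9% of 2-fold, 82.1% of 4-fold and 95.2% of 8-fold changes were recovered. For D.f. with RNase III against D.f. (17165 genes) the shares were 44.8%, 80.3% and 92.1%. For D.f. against PBS in the knockout (15294 genes) they were 44.2%, 86.9% and 93.3%, and for knockout against wild type with D.f. (15294 genes) 64.2%, 90.7% and 96.7%. Unchanged genes called made up 6.38% to 14.7% of the calls over the 9 comparisons, 7.30% and 10.3% for the first pair named and 14.7% and 13.9% for the second, so that the threshold of 0.05 understates the share of false calls in these simulations.

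The alternatives were size factors by relative log expression in edgeR, no filter on low counts beyond 1 read, DESeq2 1.42.0 with its own size factors and filtering, 1 fit over all 12 libraries on shared genes, a threshold of at least 2-fold, the estimated correlation and fry for lists, and leaving out each library in turn. Leaving out the called genes that differed 2-fold in the direction of their call between the PBS libraries of the knockout set was chosen after seeing the data. So were the alternatives for the acute phase list. Genes under the filter, such as Ifnb1 and Il13, were not tested and are given as reads. The values of 1 gene that the naming rule takes are not reported here.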

Results

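RNA from whole mouse lung was sequenced 14 to 16 h after exposure to an extract of the house dust mite Dermatophagoides farinae (D.f.) or to phosphate-buffered saline (PBS). The mice were of the B6 background and 6 to 8 weeks old. The 12 libraries form 2 sets of 6. In the RNase III set, wild-type mice received PBS (n = 2), D.f. extract (n = 2) or D.f. extract with RNase III (n = 2), an enzyme that cuts double-stranded RNA. In the knockout set, wild-type mice and mice lacking both Tlr3 and Mavs received PBS (n = 1 per genotype) or D.f. extract (n = 2 per genotype). Tlr3 is the endosomal receptor for double-stranded RNA, and Mavs is the adaptor of the cytosolic RNA sensors Ddx58 and Ifih1. Reads assigned to genes numbered 17754518 to 25714074 per library in the RNase III set and 15687699 to 20945618 in the knockout set, so that 3 reads, the limit set by a count of 0, corresponded to 0.117 to 0.191 CPM, the read count scaled to library size. Such limits cover counting error only. Levels are means ± SD over the libraries of a group. The labels do not say that replicates came from separate animals, and p-values therefore measure the spread between these libraries, which may be technical. No replicate pair was a duplicate. In the RNase III set the chi-square per degree of freedom between replicates was 46.6 for PBS, 27.7 for D.f. and 7.33 for D.f. with RNase III. In the knockout set it was 9.68 for wild-type D.f. and 34.3 for knockout D.f.

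The response of wild-type lung to the extract was measured first in the RNase III set. Genes of the interferon response were among those that rose. Cxcl10, a chemokine that attracts Cxcr3-bearing T and NK cells (chromosome 5, 92775664 to 92777915, minus strand, NCBIM37), rose from 3.11 ± 0.640 to 488 ± 64.5 CPM, a 157-fold change (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 5.9e-05). Isg15, which encodes a ubiquitin-like antiviral protein (chromosome 4, 155573533 to 155574927, minus strand), rose from 18.2 ± 13.7 to 446 ± 10.8 CPM. Irg1, the enzyme that makes itaconate in activated macrophages (chromosome 14, 103446194 to 103455790, plus strand), rose 211-fold to 85.2 ± 13.8 CPM. Of 50 tested type I interferon-stimulated genes, 49 rose and all 50 rose when adjusted over the list alone, with a median log2 fold change of 3.70. Examples are Bst2, which tethers budding virus, at 3.26 ± 0.14 (log2 fold change ± SE) and Lgals3bp at 2.71 ± 0.13. Of 31 interferon-gamma-associated genes, 30 rose (31 adjusted over the list alone), among them the guanylate-binding protein gene Gbp2 at 3.70 ± 0.16. All 9 interferon-induced chemokines and all 20 genes of MHC class I presentation rose, including the immunoproteasome subunit gene Psmb8 at 2.26 ± 0.14. Of 24 nucleic acid sensors and adaptors, 17 rose (18 adjusted over the list alone), such as the Z-form nucleic acid sensor gene Zbp1 at 4.97 ± 0.29 and Ifih1 at 2.55 ± 0.17. Tlr3 itself rose by 1.49 ± 0.19. Camera calls with the preset correlation were kept with an estimated correlation by the chemokines and by MHC class I presentation (adjusted p = 0.0262 each) and lost by the interferon-stimulated genes (adjusted p = 0.0764 with an estimated correlation), the interferon-gamma-associated genes (adjusted p = 0.107) and the sensors (adjusted p = 0.152). By the rotation test fry, the interferon-stimulated genes, the interferon-gamma-associated genes and the sensors were called (fry adjusted p = 0.0106, 0.0137 and 0.0140).

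Inflammatory mediators were tested in the same libraries. Saa3, an acute phase protein of macrophages and epithelium (chromosome 7, 53967368 to 53971046, minus strand), rose from 10.5 ± 4.29 to 758 ± 83.9 CPM in the RNase III set. Of 22 acute phase and secreted defence genes 13 rose (16 adjusted over the list alone, median 1.88, adjusted p = 0.128 with an estimated correlation), such as Orm1 at 4.01 ± 0.34. Of 22 neutrophil chemokines and acute cytokines 15 rose (18 adjusted over the list alone, adjusted p = 0.225 with an estimated correlation), among them Ccl4 at 5.49 ± 0.36, Ccl20 at 3.67 ± 0.35 and Il1b at 3.48 ± 0.39. The interleukin 1 receptor antagonist gene Il1rn rose by 3.83 ± 0.15, and 15 of 21 genes of the inflammasome and interleukin 1 pathway rose (17 adjusted over the list alone, adjusted p = 0.0262 with an estimated correlation). Cxcl1 and Il6 rose by 3.58 ± 0.64 and 4.11 ± 0.60. Neither was called without D.f. replicate 3 (adjusted p = 0.0593 and 0.0566). Ifng, measured at 0.0960 ± 0.0583 CPM with PBS and 1.49 ± 0.419 CPM with D.f., rose by 3.83 ± 0.59, a call that was lost without D.f. replicate 4 (adjusted p = 0.0821). Among markers of immune cells, 14 of 23 NK cell and cytotoxic genes rose (20 adjusted over the list alone, adjusted p = 0.187 with an estimated correlation), including the granzyme gene Gzmb at 2.91 ± 0.24. Of 22 genes of monocytes and interstitial macrophages 7 rose and 1 fell (10 and 1 adjusted over the list alone, adjusted p = 0.22 with an estimated correlation), including Ly6c2, a marker of inflammatory monocytes with close copies in the Ly6 family, at 4.68 ± 0.21. Of the genes linked to allergic inflammation, the eosinophil chemokine gene Ccl11 rose from 3.001 ± 0.607 to 7.72 ± 1.42 CPM (log2 fold change 1.36 ± 0.29, adjusted p = 0.0262). Its call was lost without D.f. replicate 3 (adjusted p = 0.165) or 4 (0.0956), without D.f. with RNase III replicate 5 (0.0545) or 6 (0.0588), and in 1 fit over all 12 libraries (0.160). The alarmin gene Il33 measured 83.8 ± 45.2 CPM with PBS and 151 ± 23.4 CPM with D.f. (adjusted p = 0.154), and the mucin gene Muc5ac 3.08 ± 2.5 and 7.86 ± 2.21 CPM (adjusted p = 0.182). Il13 was too low to be tested, with at most 9 reads in any library.

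Markers of fibroblasts and other lung cells were tested in the same comparison of the RNase III set. Of 28 fibroblast and matrix genes 12 fell and none rose over all genes tested (16 fell and 1 rose adjusted over the list alone, median -0.79, adjusted p = 0.261 with an estimated correlation). Inmt, a methyltransferase abundant in lung, fell by 2.53 ± 0.29 on the log2 scale. Of 11 mesothelial genes 5 fell (7 adjusted over the list alone, adjusted p = 0.285 with an estimated correlation), including the uroplakin gene Upk3b, which fell by 1.55 ± 0.19. Of 28 endothelial genes 5 fell (adjusted p = 0.528 with an estimated correlation), and of 19 genes each of smooth muscle and pericytes and of alveolar type 1 cells 3 fell (adjusted p = 0.155 and 0.528 with an estimated correlation). Among the largest falls were the glutamate receptor subunit gene Gria1, from 42.4 ± 13.8 to 4.64 ± 1.15 CPM, and the collagen-tail gene of acetylcholinesterase, Colq, from 28.7 ± 6.74 to 4.31 ± 0.607 CPM. Nr1d1, a repressor of the circadian clock, fell by 2.84 ± 0.36 to 3.48 ± 0.484 CPM, and its call was lost without D.f. replicate 4 (adjusted p = 0.0589). Cardiac muscle genes differed within the PBS pair. Their median lay 3.71 higher on the log2 scale in PBS replicate 2 than in replicate 1, and 1 of 22, Myh7, fell with D.f. (log2 fold change -2.46 ± 0.23). Over all 17165 genes tested 1118 rose and 772 fell (edgeR, adjusted p under 0.05), and DESeq2 called 2417. The count was 813 without D.f. replicate 3, 584 without D.f. replicate 4, 987 and 973 without D.f. with RNase III replicate 5 and 6, and 3071 without PBS replicate 2.

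Whether the same extract given with RNase III still changed the lung was tested against the same PBS libraries. Saa3 rose to 288 ± 40.2 CPM, 27.6-fold above PBS (edgeR's quasi-likelihood test, adjusted p = 0.0133), and was the 1 gene called of 17165. Isg15 measured 18.3 ± 0.213 CPM against 18.2 ± 13.7 with PBS, a log2 difference of 0.02 ± 0.46. Cxcl10 measured 9.01 ± 0.565 against 3.11 ± 0.640 CPM (log2 difference 1.55 ± 0.20, adjusted p = 0.216). Tlr3 measured 40.5 ± 0.815 against 37.6 ± 9.76 CPM. None of the 50 interferon-stimulated genes was called over all genes, 4 rose adjusted over the list alone and 35 were positive (median 0.17). Camera called this list higher at its preset correlation (adjusted p = 1.3e-08) and not with an estimated one (adjusted p = 0.506). Of 31 interferon-gamma-associated genes 0 were called, 1 rose adjusted over the list alone and 22 were positive (median 0.31). That list was also called by camera at the preset correlation (adjusted p = 5.8e-09) and not with an estimated one (adjusted p = 0.506). Of 22 acute phase and secreted defence genes 1 rose over all genes and 11 rose adjusted over the list alone (median 0.87, with 1.65 without PBS replicate 2 and 0.512 without D.f. with RNase III replicate 6). The camera call of that list was lost with an estimated correlation (adjusted p = 0.17). Of 22 neutrophil chemokines and acute cytokines 0 were called, 4 rose adjusted over the list alone and 19 were positive (median 1.09, adjusted p = 0.436 with an estimated correlation). Of 9 interferon-induced chemokines 0 were called, 4 rose adjusted over the list alone and 8 were positive (median 0.97, adjusted p = 0.163 with an estimated correlation). Acute phase genes not called over all genes include Saa1 at 4.19 ± 0.45, Orm1 at 3.16 ± 0.34 and Lcn2, a bacterial siderophore-binding protein, at 2.51 ± 0.31. Cardiac muscle genes, which differed within the PBS pair, were lower in all 22 members (median -1.89, adjusted p = 0.506 with an estimated correlation, 0 called), and so were all 13 adipose tissue genes (median -1.65, adjusted p = 0.614 with an estimated correlation, 0 called), whose relative log2 level was -1.11 and 1.19 in PBS replicates 1 and 2. The PBS libraries also differed in Psca, a surface antigen gene, which measured 8.92 CPM in PBS replicate 1 and at most 0.21 CPM in the other 5 libraries of the set. In all, 835 genes (4.86%) had an unadjusted p under 0.05, where chance alone gives about 5%, and DESeq2 called 50. The count of called genes was 188 without PBS replicate 1 and 62 without PBS replicate 2. It was 0 without either D.f. library (replicates 3 and 4) or without either library of D.f. with RNase III (replicates 5 and 6). The call of Saa3 was lost in those last 4 fits, with adjusted p between 0.0562 and 0.155 and log2 fold changes of 4.63 to 4.92.

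The direct comparison of D.f. with RNase III against D.f. alone asked which parts of the response differed when RNase III was given with the extract. No group received PBS with RNase III. An effect of cutting double-stranded RNA can therefore not be told apart from other effects of adding the enzyme. Interferon-stimulated genes were lower with RNase III. Cxcl10 was 53.7-fold lower (log2 fold change -5.75 ± 0.20, edgeR's quasi-likelihood test, adjusted p = 0.00017), Cxcl9 changed by -5.03 ± 0.29, and Oas3, which makes the activator of RNase L, by -4.85 ± 0.21. Isg15 fell by 4.59 ± 0.50 on the log2 scale, with adjusted p = 0.0568 without replicate 5. Of 50 interferon-stimulated genes 49 fell (50 adjusted over the list alone, median -3.33, adjusted p = 0.0596 with an estimated correlation). Of 31 interferon-gamma-associated genes 30 fell (30 adjusted over the list alone, adjusted p = 0.0982 with an estimated correlation), of 9 interferon-induced chemokines 8 fell (9 adjusted over the list alone, adjusted p = 0.0318 with an estimated correlation), and of 20 genes of MHC class I presentation all 20 fell (adjusted p = 0.0332 with an estimated correlation). Of 24 sensors and adaptors 15 fell (16 adjusted over the list alone, adjusted p = 0.148 with an estimated correlation), including Zbp1 at -4.09 and Dhx58, a regulator of RNA sensing, at -3.40. Of 22 neutrophil chemokines and acute cytokines 9 fell (14 adjusted over the list alone, adjusted p = 0.297 with an estimated correlation), such as Ccl4 at -3.50, and of 22 acute phase genes 6 fell (8 adjusted over the list alone, adjusted p = 0.297 with an estimated correlation). Saa3 was 2.61-fold lower (log2 fold change -1.38, adjusted p = 0.024), a call lost without any of the D.f. libraries (replicates 3 and 4) or of those with RNase III (replicates 5 and 6), with adjusted p between 0.107 and 0.261, and Cxcl1 had a log2 difference of -1.86 ± 0.57 (adjusted p = 0.11). Ccl11 fell by 1.90 ± 0.30 on the log2 scale to 2.05 ± 0.490 CPM (adjusted p = 0.0109), a call lost without replicate 3 (adjusted p = 0.0870), 4 (0.0574), 5 (0.149) or 6 (0.0701) and in 1 fit over all 12 libraries (0.0862).

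Markers of lymphocytes were tested in the same RNase III comparison. Of 23 NK cell and cytotoxic genes 13 fell (20 adjusted over the list alone, adjusted p = 0.196 with an estimated correlation), including Gzmb at -3.24 ± 0.25 and the interleukin 2 receptor gene Il2rb at -2.02. Of 25 T cell genes 12 fell (18 adjusted over the list alone) and of 21 B cell and plasma cell genes 8 fell (16 adjusted over the list alone), both with adjusted p = 0.297 with an estimated correlation. With D.f. against PBS, 1 of the 21 B cell and plasma cell genes had risen (median 0.35). With RNase III against PBS, 19 of 21 were negative and 0 called (median -0.50, 6 lower adjusted over the list alone, adjusted p = 0.436 with an estimated correlation). The monocyte marker Ly6c2 changed by -4.05. In the other direction, 6 of 28 fibroblast genes rose (12 adjusted over the list alone, adjusted p = 0.297 with an estimated correlation) and 3 of 11 mesothelial genes rose (5 adjusted over the list alone, adjusted p = 0.465 with an estimated correlation). Sept3, a septin gene, rose 9.35-fold, from 0.689 ± 0.0736 to 6.43 ± 0.523 CPM (adjusted p = 0.0011). Beside these groups, cardiac muscle genes were lower in 21 of 22 members (median -1.97, adjusted p = 0.648 with an estimated correlation), with 1 called, in the other direction, and adipose tissue genes in all 13 (median -1.93, adjusted p = 0.602 with an estimated correlation, 0 called). In all, 413 genes rose and 833 fell with RNase III, and DESeq2 called 1893. The count was 2874 without PBS replicate 1 or without PBS replicate 2, 537 without replicate 3, 359 without replicate 4, 146 without replicate 5 and 238 without replicate 6.

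**Figure D1:**
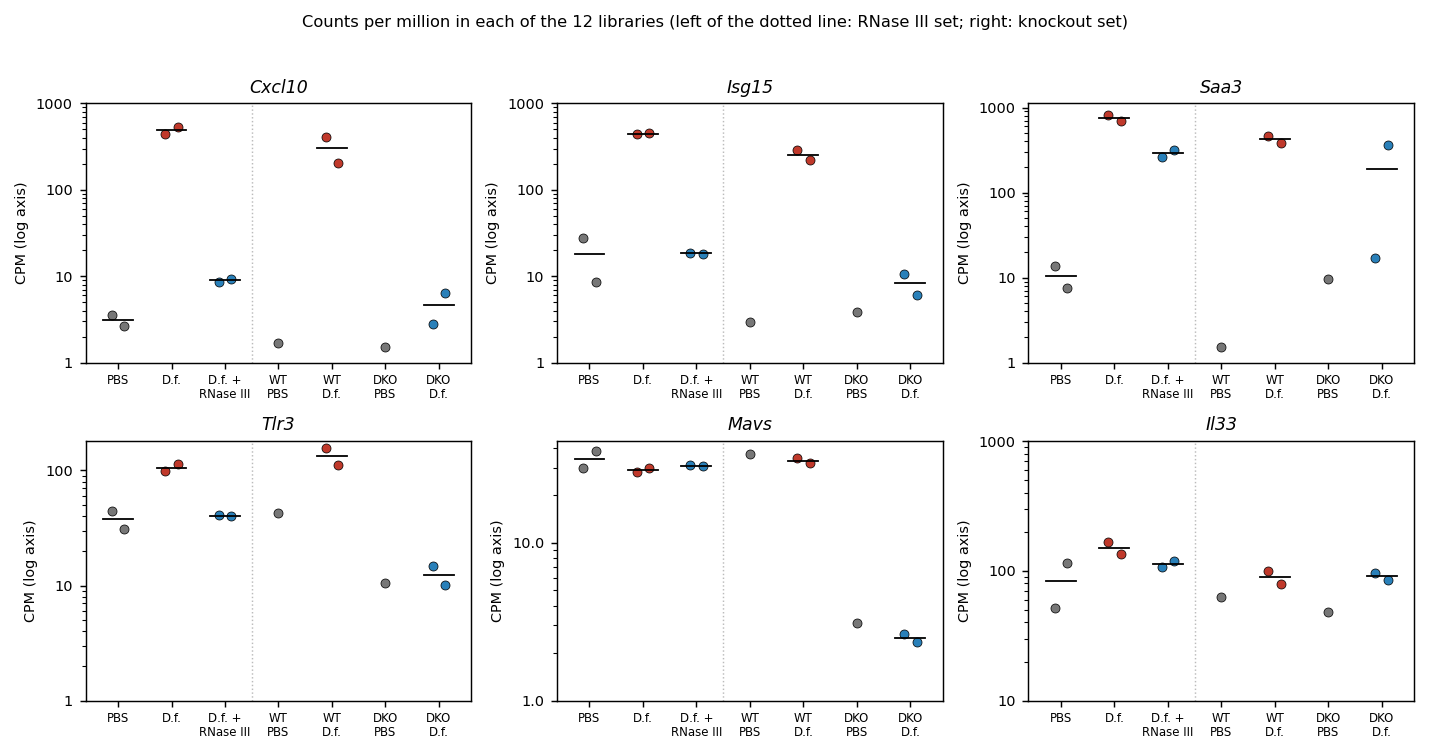
CPM of Cxcl10, Isg15, Saa3, Tlr3, Mavs and Il33 in each library on a log axis, with points for libraries and bars for group means in the 7 groups. Cxcl10 had means of 488 CPM with D.f. and 9.01 CPM with D.f. and RNase III, and in the knockout set 309 CPM in wild type and 4.61 CPM in the knockout with D.f.

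For the knockout set, the targeted genes were examined in every library. Mavs (chromosome 2, 131059799 to 131073761, plus strand) measured 36.3 CPM in wild-type PBS, 33.3 ± 1.52 CPM in wild-type D.f., 3.08 CPM in knockout PBS and 2.51 ± 0.218 CPM in knockout D.f. Tlr3 (chromosome 8, 46481019 to 46495962, minus strand) measured 42.4 CPM in wild-type PBS, 134 ± 31.1 CPM in wild-type D.f., 10.5 CPM in knockout PBS and 12.4 ± 3.35 CPM in knockout D.f. Counts cover whole genes, so reads from exons outside a deleted part remain in them. Between the D.f. groups Mavs was 13.3-fold lower (edgeR's quasi-likelihood test, adjusted p = 0.0041) and Tlr3 10.8-fold lower (adjusted p = 0.0099) in the knockout. Without wild-type D.f. replicate 3 these were adjusted p = 0.0566 for Mavs and 0.101 for Tlr3, and without replicate 4 Tlr3 had adjusted p = 0.0524. In the 6 wild-type libraries of the RNase III set Mavs had group means of 29.0 to 34.0 CPM.

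The response to D.f. extract was then measured in wild-type mice of the knockout set. Isg15 rose from 2.96 to 254 ± 49.0 CPM (85.8-fold, edgeR's quasi-likelihood test, adjusted p = 0.017) and Cxcl10 from 1.71 to 309 ± 146 CPM (180-fold, adjusted p = 0.030). Of 52 interferon-stimulated genes 35 rose (52 adjusted over the list alone, median 3.72, adjusted p = 0.339 with an estimated correlation), including Ifit1, which binds viral RNA caps, at 5.84 ± 0.36. Of 23 acute phase genes 4 rose (16 adjusted over the list alone, adjusted p = 0.377 with an estimated correlation), including Saa1 at 5.45 ± 0.34, whose reads can be shared with its near copy Saa2. Of 30 cell cycle genes 4 rose (18 adjusted over the list alone, median 1.21, adjusted p = 0.377 with an estimated correlation), among them Top2a, the DNA topoisomerase of dividing cells, at 1.70 ± 0.19. Among the largest falls, Nr1d1 fell from 71.7 to 21.1 ± 1.86 CPM. Of 25 genes of ciliated cells 2 fell (14 adjusted over the list alone, median -0.59, adjusted p = 0.377 with an estimated correlation), and the ciliary dynein gene Dnahc6 fell by 1.32 ± 0.10. Of 28 fibroblast and matrix genes 1 rose and 0 fell here (1 and 0 adjusted over the list alone, 15 of 28 positive, median 0.16). Cardiac muscle genes had a median of -0.60 with 0 called. In all 211 genes rose and 21 fell of 15294, and DESeq2 called 649. Without replicate 3 or without replicate 4 of wild-type D.f. the count was 0, while the log2 fold change of Isg15 was 6.18 (adjusted p = 0.151) and 6.58 (adjusted p = 0.0953). The count was 3150 without knockout D.f. replicate 5 and 2977 without replicate 6.

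In the knockout mice, no gene was called for D.f. against PBS by edgeR's quasi-likelihood test, 847 genes (5.54%) had an unadjusted p under 0.05 and DESeq2 called 37. Isg15 measured 3.84 CPM with PBS and 8.24 ± 3.16 CPM with D.f. (log2 difference 1.09 ± 0.41), and Cxcl10 1.51 and 4.61 ± 2.61 CPM. Of 52 interferon-stimulated genes 0 were called and 1 rose adjusted over the list alone, while 50 had a positive log2 fold change (median 0.55). Camera called this list higher at its preset correlation (adjusted p = 4.0e-13) and not with an estimated one (adjusted p = 0.464). Of 23 acute phase genes 0 were called, 8 rose adjusted over the list alone and all 23 were positive (median 1.31, adjusted p = 0.351 with an estimated correlation), including Lcn2 at 3.34 ± 0.87. Of 18 glucocorticoid-induced genes 0 were called and 11 rose adjusted over the list alone (median 1.23, adjusted p = 0.351 with an estimated correlation), such as Tsc22d3, a leucine zipper gene induced by glucocorticoids, at 1.00 ± 0.11. Of 22 type 2 effector genes 0 were called, 3 rose adjusted over the list alone and 20 were positive (median 1.41, adjusted p = 0.351 with an estimated correlation). Of 21 NK cell and cytotoxic genes 0 were called, 1 fell adjusted over the list alone and 20 were negative (median -1.06, adjusted p = 0.351 with an estimated correlation). Il33 measured 48.1 CPM with PBS and 91.2 ± 8.31 CPM with D.f. The knockout D.f. libraries differed from each other. Saa3 measured 17 and 366 CPM in replicates 5 and 6, with 9.75 CPM in knockout PBS, and the relative log2 level of the interferon-gamma-associated list was 0.77 and -1.55. Leaving out replicate 5 or replicate 6 left 1 knockout library per treatment. The spread in those fits came from the wild-type D.f. pair alone, so their counts of called genes do not measure spread in the knockout.

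Knockout and wild-type lungs were then compared under D.f. extract, which asks what the response lost without Tlr3 and Mavs. Cxcl10 fell by 6.06 ± 0.54 on the log2 scale (66.6-fold, edgeR's quasi-likelihood test, adjusted p = 0.014), and Isg15 by 4.95 ± 0.30 (adjusted p = 0.0062). The antiviral genes Ifit1, Ifit2 and Oasl1 changed by -4.65 ± 0.24, -4.80 ± 0.24 and -5.44 ± 0.30. Of 52 interferon-stimulated genes 46 fell (50 adjusted over the list alone, median -2.94, adjusted p = 0.36 with an estimated correlation). Of 24 sensors and adaptors 10 fell, the targets Tlr3 and Mavs among them (20 adjusted over the list alone, adjusted p = 0.36 with an estimated correlation). Of 9 interferon-induced chemokines 6 fell (8 adjusted over the list alone, adjusted p = 0.36 with an estimated correlation), of 18 genes of MHC class I presentation 9 (15 adjusted over the list alone, adjusted p = 0.479 with an estimated correlation), and of 29 interferon-gamma-associated genes 5 (9 adjusted over the list alone, adjusted p = 0.515 with an estimated correlation). Ccl5, a chemokine for T cells and eosinophils (chromosome 11, 83339280 to 83344020, minus strand), fell by 3.03 ± 0.14. Of 23 acute phase genes 3 fell (4 adjusted over the list alone, adjusted p = 0.643 with an estimated correlation), such as Saa1, which fell by 1.80 ± 0.18. Of 28 fibroblast and matrix genes 4 fell and 0 rose (7 fell adjusted over the list alone, adjusted p = 0.606 with an estimated correlation). Il33 did not pass the test (91.2 ± 8.31 against 89.7 ± 14.6 CPM, log2 difference 0.02 ± 0.14, adjusted p = 0.96).

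Some genes were higher in the knockout under D.f. extract. The scavenger receptor gene Cd163 was higher by 2.71 ± 0.33 on the log2 scale (edgeR's quasi-likelihood test, adjusted p = 0.026) and Nr1d1 by 1.67 ± 0.12 (adjusted p = 0.0096). Of 30 cell cycle genes 4 fell (13 adjusted over the list alone, adjusted p = 0.479 with an estimated correlation), including Top2a, which fell by 1.11. Of 21 cardiac muscle genes 6 fell (18 adjusted over the list alone, median -2.19, adjusted p = 0.479 with an estimated correlation), such as the creatine kinase gene Ckm, which fell by 3.18 ± 0.37. In the PBS libraries, with no replicates, the cardiac list was also lower in the knockout (median -2.5). Several of the largest differences were present with PBS too. The RNase P RNA-like gene Rprl3, uncertain because of near-identical copies, measured 329 CPM in wild-type PBS, 325 ± 19.2 CPM in wild-type D.f., 0.629 CPM in knockout PBS and 0.566 ± 0.0485 CPM in knockout D.f. The GTPase gene Rab6b measured 15.6, 7.14 ± 0.858, 79.8 and 53.2 ± 11.1 CPM in the same order. In all 79 genes were higher and 308 lower in the knockout, and DESeq2 called 732. Of these, 72 and 263 were less than 2-fold apart in that direction between the PBS libraries. The count was 7 without wild-type D.f. replicate 3, 17 without replicate 4, 3048 without knockout D.f. replicate 5 and 2479 without replicate 6. Ifit1, Ifit2, Oasl1 and Rprl3 were called without either wild-type library. Without wild-type D.f. replicate 3, the adjusted p was 0.107 for Cxcl10, 0.0791 for Isg15, 0.0784 for Ccl5, 0.305 for Cd163 and 0.172 for Nr1d1, and without replicate 4 it was 0.0571 for Cxcl10, 0.0516 for Isg15, 0.231 for Cd163 and 0.0945 for Nr1d1.

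Whether genotype changed the response itself was tested as the genotype by treatment interaction. Ccl5 was the 1 gene called by edgeR's quasi-likelihood test (log2 difference of responses -4.92 ± 0.25, adjusted p = 0.0429). It measured 3.24 CPM in wild-type PBS, 47.3 ± 4.69 CPM in wild-type D.f., 12 CPM in knockout PBS and 5.78 ± 0.323 CPM in knockout D.f. The call was lost without wild-type D.f. replicate 3 (adjusted p = 0.41) or replicate 4 (adjusted p = 0.287). Of 52 interferon-stimulated genes 47 fell adjusted over the list alone (median -2.95, adjusted p = 0.256 with an estimated correlation). Isg15 and Cxcl10 had differences of -5.33 ± 0.60 (adjusted p = 0.149) and -5.88 ± 1.28 (adjusted p = 0.249). In all 1481 genes (9.68%) had an unadjusted p under 0.05 and DESeq2 called 212. With edgeR the count was 0 without either wild-type D.f. library (replicates 3 and 4), 1666 without knockout D.f. replicate 5 and 1238 without replicate 6. In simulated data for this comparison over 15294 genes, 7.76% of 2-fold and 83.9% of 8-fold changes were recovered.

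**Figure D2:**
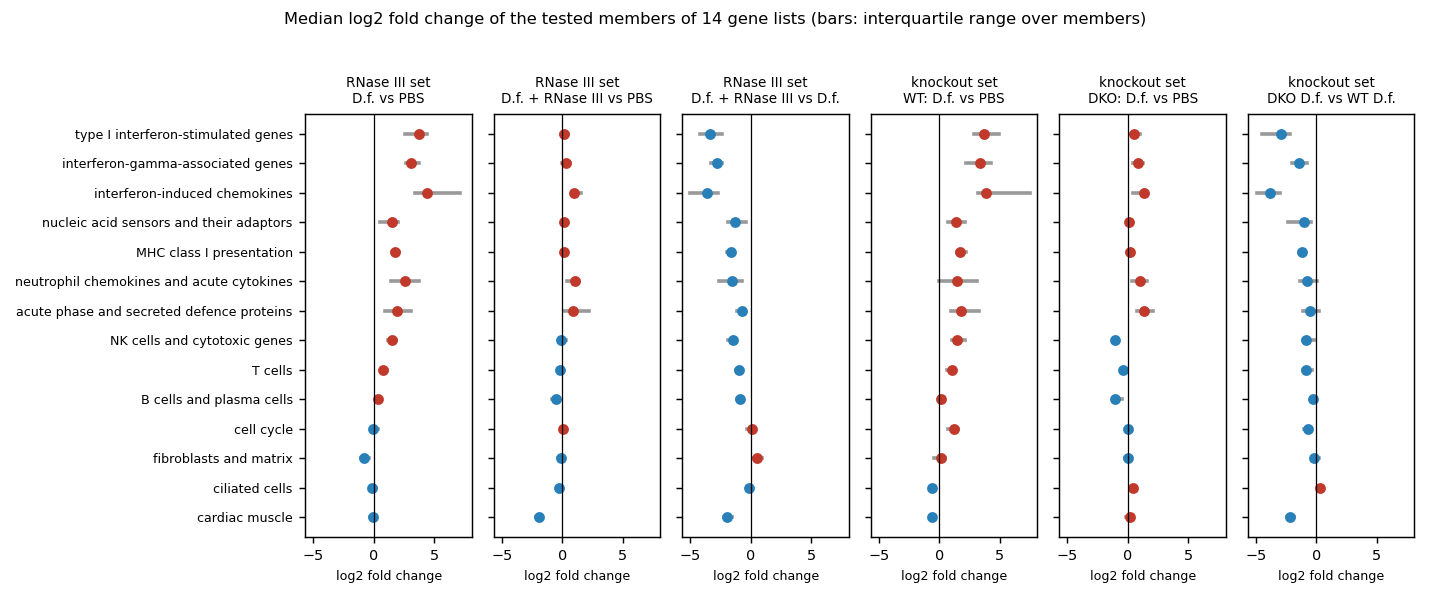
Median log2 fold change (points) with the interquartile range of tested members (lines) for 14 gene lists in 6 comparisons. Interferon-stimulated genes had medians of 3.70 for D.f. against PBS, 0.17 for D.f. with RNase III against PBS and -3.33 between those treatments, and -2.94 for knockout against wild type with D.f.

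The 7 wild-type libraries with PBS or D.f. of both sets were also fitted together, with the set as a term. Cxcl10 rose 164-fold (edgeR's quasi-likelihood test, adjusted p = 2.3e-05), and all 51 tested interferon-stimulated genes rose (median 3.89, adjusted p = 0.0493 with an estimated correlation), as did all 31 interferon-gamma-associated genes (adjusted p = 0.0493 with an estimated correlation). Of 22 acute phase genes 15 rose (18 adjusted over the list alone, adjusted p = 0.0493 with an estimated correlation). Tlr3 rose by 1.55 ± 0.17 and Ifng by 3.47 ± 0.56. Il33 (log2 difference 0.70 ± 0.26, adjusted p = 0.108) and Il6 (2.00 ± 0.95, adjusted p = 0.202) were not called. Fabp1, a fatty acid-binding protein, fell by 3.68 ± 0.32 and Nr1d1 by 2.39 ± 0.30. Over 14953 genes 1372 rose and 880 fell. The count was 1112 without D.f. replicate 3 and 1247 without D.f. replicate 4 of the RNase III set, and 1232 without wild-type D.f. replicate 3 of the knockout set. The difference between the responses of the 2 sets was tested separately. edgeR called 0 of 15481 genes, with 856 (5.53%) at an unadjusted p under 0.05 and 52 called by DESeq2, and the count was 125 without PBS replicate 2 of the RNase III set. Of 28 fibroblast and matrix genes 0 were called, and 12 had a lower response in the RNase III set adjusted over the list alone (median difference -0.71, camera adjusted p = 1.0e-19, adjusted p = 0.0833 with an estimated correlation). The sets also differ in the number of genes listed (33924 and 22609), and set and list of genes cannot be told apart.

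The effects of RNase III and of the knockout were then set side by side. These fits share no library. The 208 tested genes that rose with D.f. in the knockout set's wild type had a median log2 fold change of -1.70 with RNase III (interquartile range -2.53 to -1.11), and 176 of them fell (camera p = 7.3e-184, p = 0.0018 with an estimated correlation). Conversely, the 1036 tested genes that rose with D.f. in the RNase III set had a median of -0.56 in knockout against wild type, and 210 fell (p = 0.0608 with an estimated correlation). The 20 tested genes that fell with D.f. in the knockout set's wild type had a median of 0.49 with RNase III, and 7 rose (p = 0.0115 with an estimated correlation), while the 740 that fell in the RNase III set had a median of 0.21 in knockout against wild type, with 34 higher and 3 lower (p = 0.374 with an estimated correlation). Across 14706 genes the RNase III and knockout effects had a Pearson r of 0.558 and a Spearman rho of 0.374, where genes are not independent replicates. Without the filter on low counts the Pearson r was 0.285. In both comparisons 203 genes were lower, against 15.9 for independent lists (Fisher's exact test, p = 1.5e-192), and 24 were higher, against 2.12 (Fisher's exact test, p = 2.8e-19). None was called in opposite directions. Those lower in both include Ifit2 (-4.75 ± 0.32 with RNase III and -4.80 ± 0.24 in the knockout), Irf7, the transcription factor that amplifies interferon production (-4.77 ± 0.48 and -4.76 ± 0.38), Ccl5 (-2.69 ± 0.26 and -3.03 ± 0.14) and Apod, an apolipoprotein (-4.23 and -3.50). This was 1 of 6 pairs of comparisons examined in this way. The responses to D.f. of the 2 sets had r = 0.722, with 189 genes that rose in both against 14.7 for independent lists. The responses to D.f. and to D.f. with RNase III share their PBS libraries. They had r = 0.435, where unchanged groups simulated against these libraries gave 0.503, and a covariance of 0.141 against 0.0584 simulated. The 1 gene called in both, Saa3, compares with 0.46 simulated and 0.0651 for independent lists. With 2 PBS libraries the controls could not be split, and part of any excess may come from the shared controls. The response to D.f. with RNase III had r = 0.134 with the knockout's response to D.f. and r = 0.328 with that of the knockout set's wild type, and the D.f. response of the RNase III set had r = 0.365 with the knockout's. In these 3 pairs 0 genes were called in both, and in the first and last the knockout's response had 0 calls.

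**Figure D3:**
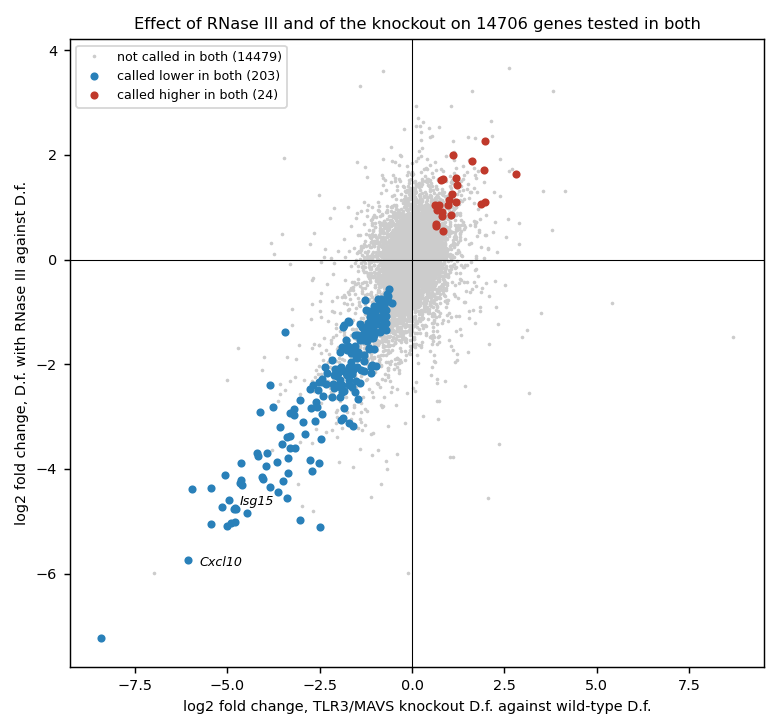
Log2 fold change of knockout against wild type with D.f. (horizontal axis) and of D.f. with RNase III against D.f. (vertical axis), with 1 point for each of 14706 genes. The 203 genes called lower in both (blue) lie at the lower left, the 24 called higher in both (red) at the upper right, and the others are grey.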

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

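Of the tests given here, the refits of other splits of the 7 wild-type libraries were planned; the restriction of these to splits within the sets, and the tests on genetic background, acute phase genes and cardiac muscle, were chosen after the result was seen. The responses of the genotypes to D.f. extract differed, by the interaction test, in 1 gene and in 12 lists whose median difference was at least 1 on the log2 scale. The gene was Ccl5 (-4.92, edgeR adjusted p = 0.0429). By camera with its preset correlation the knockout's response was lower in type I interferon-stimulated genes (median -2.95, camera adjusted p = 1.1e-137), interferon-gamma-associated genes (-2.61, 3.5e-17), nucleic acid sensors and their adaptors (-1.29, 1.7e-26), interferon-induced chemokines (-3.15, 3.6e-20) and MHC class I presentation (-1.56, 5.0e-25), with adjusted p between 0.256 and 0.465 with an estimated correlation and with 47 of 52, 5 of 29, 15 of 24, 3 of 9 and 14 of 18 genes lower adjusted over the list alone. The camera result was also lower in NK cell and cytotoxic genes (-2.49, 2.9e-36), T cells (-1.38, 5.7e-17), B cells and plasma cells (-1.07, 3.3e-06), neutrophils (-1.06, 0.0031) and the cell cycle (-1.15, 4.0e-17), with adjusted p between 0.256 and 0.596 with an estimated correlation and with 18 of 21, 13 of 24, 0 of 21, 0 of 16 and 8 of 30 genes lower adjusted over the list alone. It was higher in ciliated cells (1.02, 1.5e-23, 16 of 25 genes) and adipose tissue (1.36, 4.0e-06, 0 of 11 genes), both with adjusted p = 0.256 with an estimated correlation. Each genotype had 1 PBS library. Compared directly under D.f. extract, the neutrophil list was higher in the knockout (median 0.46, 12 of 16 genes positive). Medians there were -0.25 for B cells and plasma cells and -0.06 for adipose tissue. The interaction values of these lists therefore rest largely on the single PBS libraries. In the same direct comparison the medians were -0.86 for NK cell and cytotoxic genes, -0.87 for T cells, -0.68 for the cell cycle and 0.32 for ciliated cells. They were -1.46 for interferon-gamma-associated genes, -1.16 for MHC class I presentation and -1.02 for sensors and adaptors. All of these were smaller in size than the interaction medians, so that part of those interaction values rests on the single PBS libraries too. For type I interferon-stimulated genes and interferon-induced chemokines the direct medians were -2.94 and -3.79. Between the sets, the wild-type response of the cell cycle list differed (median -1.04, camera adjusted p = 1.1e-13, adjusted p = 0.618 with an estimated correlation), lower in the RNase III set.

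Reads of type I interferon genes appeared outside the tested genes. The D.f. libraries of the RNase III set held 17 reads of Ifnb1 and 4 reads of Ifna2, and the PBS libraries of that set held 0. In wild-type D.f. libraries of the knockout set Ifnb1 had 2 and 0 reads.

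The D.f. response of wild type over both sets called 2252 genes. Of 34 splits of the 7 libraries into 3 and 4 that could be fitted (1 more could not), 1, the real one, gave as many, and the highest of the others called 3. Because the set is a term of the fit, splits that change the numbers of libraries per set are no fair comparison, and the 5% criterion planned over all splits does not apply. The splits that keep those numbers are 18, too few for a share under 5%, and the highest of the others among them called 0.

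The first pattern is a group of genes in which every wild-type library of the knockout set lay at least 1 on the log2 scale beyond every knockout library, whatever the treatment. There were 56, of which 30 followed cardiac muscle, and other splits of the 6 libraries gave up to 43. Without genes that followed cardiac muscle there were 26, and another split gave 42. Those splits are not chance splits, since some put both wild-type D.f. libraries on 1 side and so carry the D.f. response. The count alone therefore cannot show whether the genotype separated more genes than chance would. Of 19 genes with a position, other than the targets, that did not follow cardiac muscle, 15.8% lay within 20 Mb of Mavs or Tlr3 against 2.73% of measured genes (one-sided Fisher's exact test, p = 0.0104), in line with DNA carried with the targeted loci, but 16 lay outside, which this cannot account for. Background that differs apart from the knockout is a candidate explanation, since in 14 of these 16 genes PBS replicate 1 of the RNase III set was the most wild-type-like of its 6 libraries; Psca measured 8.92 CPM there and at most 0.21 CPM in the other 5. Background marked by these 16 genes would not by itself account for the lower interferon-stimulated genes. Without PBS replicate 1, the median D.f. response of that list in the RNase III set was 4.11 (lower quartile 2.78). In the knockout it was 0.55 (upper quartile 1.02). Background that the 16 genes do not mark stays open, and Rprl3 and Rprl2 were not measured in the RNase III set.

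The second pattern is the acute phase response left after RNase III, with 11 of 22 genes higher adjusted over the list alone (median 0.87). Neutrophil chemokines and acute cytokines (median 1.09) and interferon-induced chemokines (median 0.97) also lay above PBS, with 4 genes each higher adjusted over the list alone. None of these lists was called by camera with an estimated correlation (adjusted p = 0.170 for acute phase, 0.436 and 0.163). Testing for a shift in 1 direction, fry called 0 of 47 lists. Its mixed test, for changes in either direction, called 4 of 47. Acute phase (fry mixed adjusted p = 0.0142) and interferon-induced chemokines (0.0373) were among them, and neutrophil chemokines and acute cytokines (0.231) were not. An uneven PBS pair stays open as the cause of the acute phase rise. The median of that list was 0.601 without PBS replicate 1 and 1.65 without replicate 2, a difference of 1.05 that exceeds the lower value. Double-stranded RNA left after digestion cannot be told apart from a component that acts without Tlr3 and Mavs. The knockout's D.f. libraries lay 0.817 and 1.77 above knockout PBS in this list, the pair differed by 0.953, and the knockout's median of 1.31 rests on a single PBS library.

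The third pattern is the lower cardiac muscle signal in the knockout with D.f. (median -2.19). Unequal amounts of heart or vein muscle in the dissected tissue may account for it, since this list differed by 3.71 between the PBS libraries of the RNase III set, which share a genotype. The knockout PBS library also lay lower than wild-type PBS (-2.50), and with 1 library each the genotype stays open.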

How the results depend on the processing

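Leaving out called genes that differed 2-fold in the direction of their call between the PBS libraries of the knockout set was chosen after the result was seen. So were the alternatives for the acute phase list. The other settings were planned. No paired analysis was possible because the groups compared share fewer than 2 replicate numbers. Size factors by relative log expression moved no count of called genes by more than 1.5 times. A threshold of at least 2-fold gave 1096 genes for D.f. against PBS and 775 for RNase III against D.f. alone, and 892 over both sets. With no filter the counts were 10 for D.f. with RNase III against PBS, 391 for D.f. in wild type of the knockout set and 16 for the interaction. DESeq2 called 50, 1893, 649, 37, 732, 212 and 52 genes for D.f. with RNase III against PBS, RNase III against D.f. alone, wild type, knockout, genotype under D.f., interaction and difference between sets. A fit over all 12 libraries gave 391 for wild type and 7 for the interaction. Testing for a shift in 1 direction, fry called 19 of 47 lists for D.f. against PBS in the RNase III set. It called 12 of 47 for RNase III against D.f. alone and 0 of 47 for D.f. with RNase III against PBS. In each comparison of the knockout set it called 0 of 48. Over both sets it called 18 of 48, and for the difference between sets 0 of 48. The correlation of RNase III and knockout effects (0.558) was 0.285 without a filter and 0.780 over genes called for D.f.; the cause was not tested.

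Leaving out 1 library in turn moved the counts of called genes in both directions. With 1 replicate fewer the tests had fewer residual degrees of freedom, and the pair that lost a library no longer entered the spread shared by its set. In each comparison within a set, the highest count came without a PBS library of the RNase III set or without a knockout D.f. library. Those pairs had the largest chi-square per degree of freedom (46.6 and 34.3). In the knockout set, a fit without a D.f. library took its spread from the 1 remaining pair. The counts ranged from 584 to 3071 for D.f. against PBS in the RNase III set, 0 to 188 for D.f. with RNase III against PBS, 146 to 2874 for RNase III against D.f. alone, 0 to 3150 for wild type, 0 to 2092 for the knockout, 7 to 3048 for genotype under D.f., 0 to 1666 for the interaction, 1112 to 2425 over both sets and 0 to 125 for the difference between sets. Over both sets the count was 1247 without D.f. replicate 4 of the RNase III set and 1232 without wild-type D.f. replicate 3. Of the medians, the interferon-stimulated list ranged from -3.57 to -3.05 with RNase III and from -3.54 to -2.66 with genotype, genes that rose in the knockout set's wild type from -1.81 to -1.56 with RNase III, and the acute phase list after RNase III-treated extract from 0.51 to 1.65. Genes that rose in the RNase III set had -0.56 with genotype, past the threshold with camera's preset correlation and not with an estimated one (p = 0.0608). The correlation ranged from 0.451 to 0.607, with 0.484 without D.f. replicate 4, 0.476 without D.f. with RNase III replicate 6 and 0.476 without wild-type D.f. replicate 3. Of 17146 values for named genes, 3 called values turned direction. Tcap in D.f. against PBS was 2.46 without PBS replicate 2 and -2.13 without replicate 1, Ryr2 1.34 and -1.11, and Hdc in the knockout's response -0.44 without D.f. replicate 5 and 0.34 without replicate 6; the cause was not tested. Named genes kept their side of the threshold in 8131 fits without a library, passed it newly in 992 and lost it in 940. Without the genes 2-fold apart in the direction of their call between the PBS libraries, 335 remained called for genotype under D.f. At these depths 3 reads, 0.117 to 0.191 CPM, were the limit for genes such as Il13.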

Other observations

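All groups described here come from lists fixed before the data were examined, and the looks at single libraries in the second paragraph were chosen after the values were seen. In the D.f. libraries of the RNase III set 10 of 15 negative regulators of cytokine signalling rose (11 adjusted over the list alone, adjusted p = 0.0764 with an estimated correlation), including Cd274, the checkpoint ligand PD-L1, at 3.30 ± 0.19 (log2 fold change ± SE, edgeR). Of 27 NF-kB feedback genes and targets 19 rose (22 adjusted over the list alone, adjusted p = 0.261 with an estimated correlation), such as the inhibitor gene Nfkbie at 1.90. Type 2 effector genes were divided, with 7 of 23 higher and 2 lower (10 and 3 adjusted over the list alone, adjusted p = 0.261 with an estimated correlation). Those that rose include Timp1, an inhibitor of matrix metalloproteinases, at 3.46 and Arg1, the arginase of alternatively activated macrophages, at 2.32 ± 0.27. Of 23 club and goblet cell genes 1 rose and 5 fell (2 and 8 adjusted over the list alone, camera adjusted p = 0.0509), and the secretory cell enzyme gene Cbr2 fell by 1.74. In the knockout under D.f. extract, 1 of 16 platelet and megakaryocyte genes was higher than in wild type (6 adjusted over the list alone, median 0.66, adjusted p = 0.36 with an estimated correlation), the platelet chemokine gene Ppbp at 1.49. Ppbp was also apart with PBS, at 4.66 CPM in wild type and 13.15 CPM in the knockout, against 4.33 ± 0.0956 and 12.2 ± 0.161 CPM with D.f., and its call was lost without wild-type D.f. replicate 3 (adjusted p = 0.283) or replicate 4 (adjusted p = 0.212).

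The sets differed in sex-linked genes. Xist measured 1415 to 2176 CPM in the 6 libraries of the RNase III set and at most 0.80 CPM in the knockout set, while the Y-linked Ddx3y had 0 reads in the first and 107 to 121 CPM in the second. A difference in response between the sets cannot be told apart from sex, from the set or from the list of genes counted. Among heart markers, Myh6 measured 43.1 and 625 CPM in the PBS libraries of the RNase III set and 425 and 37.7 CPM in wild-type and knockout PBS. In the knockout with D.f., replicate 5 lay above replicate 6 in the interferon-gamma-associated list (relative log2 level 0.77 against -1.55) and below it in the acute phase list (-0.22 against 0.73).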
